A study of Mus musculus with 12 samples.

How the data were processed

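Humeri of mouse embryos at embryonic day 14.5 were profiled in 2 genotypes, wild type and Runx2-null. Each genotype had 2 RNA pools, numbered as replicates 1 and 2 in the labels. Per the labels, 10 µg of total RNA per sample was reverse transcribed, transcribed in vitro and labelled with biotin. Each of the 4 pools was hybridised to 3 types of short-oligonucleotide array, named A, B and C here, so the series holds 12 arrays. The labels call the pools biological replicates, and p-values cover no variation beyond these pools.

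The deposited values are MAS5 signals, an array intensity on a linear scale with 1 value per probe set and array; the submitters' processing notes name MAS5 and its version is not given in the sources used here. MAS5 reduces the brightness of a probe set's perfect-match and mismatch probes to 1 value. The 2% trimmed mean of every deposited array came out at 100.0 to 100.1 intensity units, so each array had been scaled as a whole and no further normalization between arrays was applied here. Signals of a probe set can be compared between arrays of 1 type only. The number of arrays, 2 per genotype and array type, limits the precision of every value.

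Probe sets were named from the platform annotation supplied with the values. Of 36701 probe sets other than controls, 29131 had 1 gene symbol, 724 had several and 6846 had none listed here. The genes of 29044 of the 1-symbol probe sets were found in a reference gene table of the mouse, assembly GRCm38.p6, and 0 symbols needed updating. Only probe sets with 1 symbol were named. Where a gene had several probe sets, the one with the highest percentile of mean log2 signal within its array type stood for the gene. Values of further probe sets are given for some of the genes whose probe sets differed. Runx2, Spp1, Bglap and Sp7 are not analysed here.

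Values were taken as log2(signal + pseudocount), with the pseudocount at the 20th percentile of each array type's values, rounded, which was 7 for A, 13 for B and 10 for C. A fold on this scale understates the change of dim probe sets. A probe set was tested if its signal lay over the 40th percentile of its array on at least 2 of the 4 arrays. The 198 control probe sets were left out, which left 23193 probe sets, 7745 on A, 7856 on B and 7592 on C. Differences are Runx2-null minus wild type. They were tested with lmFit and eBayes (trend = TRUE) of limma 3.58.1 in R 4.3.3, with 1 fit per array type and Benjamini-Hochberg adjustment over all 3 types together, at an adjusted p of 0.05. The planned design had no block, with the replicate number as a block planned beside it. All adjusted p-values in the text come from limma, and SD and SE are over n = 2 pools per genotype. For single probe sets, eBayes draws the variance behind p and SE partly from the other probe sets of the array type. With the block this prior had 12.7 degrees of freedom on A and 7.74 on B, so these p-values and SE rest mostly on other probe sets.

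Instrument settings were read from the array files for scanner and scan batch. The 12 array files fell into 2 scan batches that equalled the replicate numbers, with 1 scan day per batch and array type. Batch 1 was read at a pixel size of 3 µm with 2 scans on one scanner model, and batch 2 at 2.5 µm with 1 scan on another. Both genotypes lie in each batch, so results are given with the replicate number as a block and within each batch. Over tested probe sets, deviations of same-numbered arrays from their genotype means correlated at r = 0.764 on A, 0.595 on B and 0.06 on C. Probe sets are not independent replicates, and the labels do not say what a shared number stands for.

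Gene lists were tested with limma's camera on 1 probe set per gene, joined over array types by RNA pool, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 24 lists. A 25th list, Runx family and partner, had 2 tested genes, below the 3 needed. An estimated correlation and limma's fry test were run beside it. With the preset, camera takes its degrees of freedom from the number of genes, not of pools. With the estimate, it takes the few residual degrees of freedom that 4 pools leave, and fewer still with the block. A call can be lost by that alone. For osteoclast genes without the block the estimate was -0.09, below the preset, yet camera's unadjusted p went from 6.47e-06 to 0.043. Lists, tests and the rule for named genes were fixed before the data were examined. The rule named the 12 largest falls and rises past the threshold, filled with the lowest p-values at a log2 fold of at least 1 either way, a fixed set of skeletal genes, and per list up to 4 members past the threshold or else 2 with the lowest p. The same rule for falls and rises was applied to arrays A and B with the block after the data had been seen.

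Alternatives were quantile normalization, other pseudocounts and filters, eBayes without a trend or with robust variances, adjustment within array types, 1 joint fit, removal of probe sets whose suffix marks possible cross-hybridization, the mean of all probe sets of a gene for the lists, the block, and each pool left out. Arrays A and B alone, and array C with an exchanged pair of labels, were added after the data had been seen. The fits were tested on simulated data with 23193 probe sets, 200 of them changed in each of 5 simulations. Without the block, 0.30% of 2-fold, 13.7% of 4-fold and 73.0% of 16-fold changes were recovered and 0% of calls were false. With the block, the recovered shares were 66.0%, 93.7% and 100%, and 15.8% of calls were false, or 9.60% of calls of at least 2-fold. Camera called a shifted list of 20 genes in 5 of 5 simulations, with 1 call of an unshifted list. The simulated probe sets varied independently of each other, so this does not check camera on lists whose genes move together.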

Results

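Total RNA from humeri, the long bone of the upper forelimb, was compared between wild-type and Runx2-null mouse embryos at E14.5. The comparison addresses which transcripts of the developing bone depend on Runx2, a transcription factor that osteoblasts require and that also acts as chondrocytes mature. Each genotype was represented by 2 RNA pools, made from about 75 wild-type or about 60 Runx2-null humeri each. Every pool was hybridised to array types A, B and C, which gave 12 arrays with a median signal between 37.5 and 60.4 intensity units. The targeted gene is not analysed here, so the genotype labels were not checked against its level. Its relatives gave values without a call: the RUNX family member Runx1 had a log2 fold of -0.34 (SE 0.26, adjusted p = 0.565 with the replicate block), and Cbfb, the partner subunit of RUNX proteins, had 0.21 (SE 0.09, adjusted p = 0.239).

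Ibsp, Mmp9 and Mmp13 fell in the Runx2-null humeri, from bright wild-type signals to mean signals below the pseudocount of 7. Their single Runx2-null arrays read between 2.5 and 10, so neither the exact size nor the order of their folds is known. Ibsp, which encodes bone sialoprotein, had a signal of 1950.4 ± 383 (SD, n = 2) in wild type and 6.90 ± 2.12 in the Runx2-null pools, and fell by 7.13 on the log2 scale (SE 0.26, adjusted p = 0.00548 without a block and 4.01e-12 with it). Mmp9, a gelatinase of osteoclasts, went from 715 ± 137 to 6.70 ± 4.67 (log2 fold -5.75, SE 0.33, adjusted p = 0.0286). Mmp13, a collagenase made by hypertrophic chondrocytes and osteoblasts, went from 652 ± 245 to 5.40 ± 4.10 (log2 fold -5.72, SE 0.38, adjusted p = 0.0469). The same genes were lower within each of the 2 scan batches, Ibsp by log2 folds of -6.78 and -7.49, Mmp9 by -5.59 and -5.91, and Mmp13 by -5.68 and -5.77. Second, dimmer probe sets on array A had log2 folds of -0.95 for Ibsp (adjusted p = 0.0548 with the block) and -2.81 for Mmp9 (0.00135).

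In limma's fit without a block, 6 of 23193 probe sets passed, 0 higher and 6 lower in the Runx2-null pools, against 1792 at an unadjusted p under 0.05. Of these 1792, 1471 were on array C (19.4% of its probe sets) and 321 on arrays A and B (2.06% of 15601). The probe sets that passed on array A were Ibsp, Mmp9, Mmp13 and a probe set without a gene name here, whose signal went from 2321 ± 366 to 39.4 ± 0.57 (log2 fold -5.64, SE 0.22, adjusted p = 0.00548). On array C they were Iqgap1 and Dact3. With the replicate number, which equals the scan batch, as a block, 505 probe sets passed (223 higher, 282 lower). Array C was then set apart in the calls of single genes, for a reason given with its control probe sets. List medians and camera p-values include array C as labelled, except within scan batches and where arrays A and B alone are named. On arrays A and B, 343 of 15601 probe sets passed with the block (141 higher, 202 lower), 115 of them by at least 2-fold. They covered 226 named genes, 85 higher and 141 lower, and 44 probe sets without a name. The words rose and fell are used of these calls on arrays A and B with the block. That use was settled after both counts had been seen. In simulations with planted changes of 2-fold and more over all 3 array types, 15.8% of calls with the block were false, against 9.60% among those of at least 2-fold, so the false share was higher among smaller calls, which make up most of the 343. The count on arrays A and B with the block was 6 without limma's variance trend and 4 in a joint fit of the array types.

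**Figure D1:**
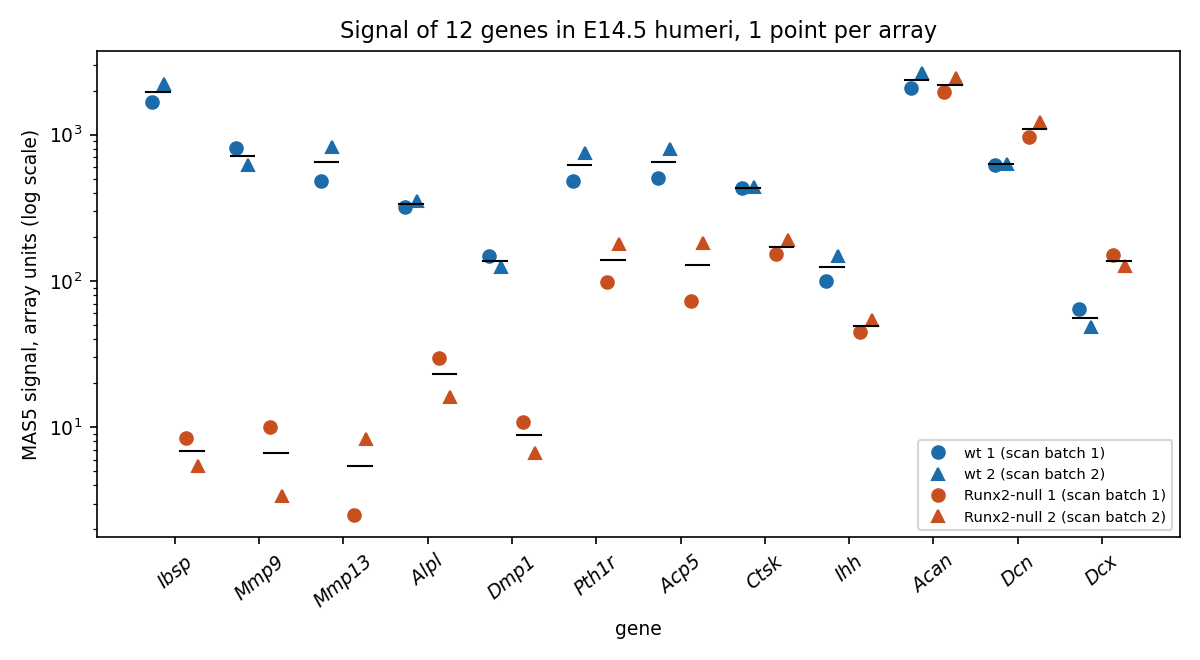
MAS5 signal on a log axis, in array intensity units, of 12 genes on each of the 4 arrays of a type; circles are replicate 1 (scan batch 1), triangles replicate 2 (scan batch 2), blue is wild type, orange is Runx2-null, and black lines are means of 2 arrays. Ibsp, Mmp9, Mmp13, Alpl and Dmp1 lie far lower in both Runx2-null pools, Acan lies at similar signals in both genotypes, and Dcn and Dcx lie higher in the Runx2-null pools.

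The osteoblast list was called lower. Of 30 listed genes, 18 were tested and 15 of these were read on arrays A and B, where 9 fell, 0 rose and 6 did not pass; adjusted over the list alone, 11 passed. Besides Ibsp, these were Alpl, the alkaline phosphatase of mineralizing cells (335 ± 21.7 to 23.0 ± 9.62, log2 fold -3.55), Dmp1, a matrix phosphoprotein of bone (136 ± 17.0 to 8.80 ± 2.97, log2 fold -3.19), and Pth1r, the receptor for parathyroid hormone and its related protein (log2 fold -2.12), with adjusted p = 1.39e-07, 5.05e-06 and 1.32e-07 with the block. Without the block, Alpl had an adjusted p = 0.0642 and Dmp1 had 0.0877. The bone matrix protein gene Omd (-1.69), the homeobox genes Dlx5 (-1.47) and Dlx3 (-1.38), the Wnt co-receptor Lrp5 (-1.44) and Col1a2 (-0.49) fell as well. For Col1a1, which encodes the major collagen of bone, the brightest probe set had a log2 fold of -0.26 (SE 0.07, adjusted p = 0.0753), while a dimmer one on array A fell by 0.82 on the log2 scale (adjusted p = 0.000576). The list had a median log2 fold of -0.60 and a mean of -1.29, and camera placed it lower (adjusted p = 2.90e-08 without and 9.67e-07 with the block). With an estimated correlation, where camera uses the few residual degrees of freedom of the 4 pools, the call was lost (adjusted p = 0.404). The median was -0.37 without wild-type replicate 1, -1.24 without wild-type replicate 2, -1.31 without Runx2-null replicate 1 and -0.31 without Runx2-null replicate 2, and the list was called lower each time. It was -0.26 with the 60th percentile filter and -1.38 on arrays A and B alone. For values within scan batches each gene was read from its brightest probe set on arrays A and B, which added genes otherwise read on array C; the 17 osteoblast genes had medians of -1.25 in batch 1 and -1.28 in batch 2.

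The list of hypertrophic chondrocytes, the enlarged cartilage cells that precede bone, was also called lower. Of 14 tested genes, 12 were read on arrays A and B, of which 8 fell, 0 rose and 4 did not pass; adjusted over the list alone, 9 passed. Ihh, the hedgehog ligand of prehypertrophic cells, went from 124 ± 34.4 to 49.1 ± 6.58 (log2 fold -1.20, SE 0.17, adjusted p = 0.00245 with the block and 0.30 without). Bmp6, another signal made in hypertrophic cartilage, fell by 1.21 on the log2 scale (SE 0.17, adjusted p = 0.00244), and the cell cycle inhibitor Cdkn1a by 1.26 (SE 0.21, adjusted p = 0.00654). Mmp13 is also on this list. Ibsp, Alpl, Pth1r and Dlx5 are on this list and on the osteoblast list, so these lists are not independent of each other. Vegfa had a log2 fold of 0.20 (SE 0.18, adjusted p = 0.634). The probe set of Col10a1, whose product is the collagen of hypertrophic cartilage, was below the filter, with signals of 6.0 and 18.3 in wild type and 5.6 and 9.1 in the Runx2-null pools. So was that of Runx3 (90.1 and 27.8, 35.1 and 34.1). Neither gene was tested, and these signals do not show how much of their transcripts was present. The list's median log2 fold was -1.24 (adjusted p = 1.82e-09 without and 1.19e-07 with the block, and 0.404 with an estimated correlation). Within scan batches 1 and 2 the medians on arrays A and B were -0.93 and -1.33.

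Osteoclast genes were lower as a list, with a median log2 fold of -0.62 over 8 tested genes (adjusted p = 5.17e-05 without and 0.00116 with the block). With an estimated correlation this was adjusted p = 0.404. The median moved with the genes that entered, to -0.25 without the filter or with the 60th percentile filter and to -0.98 on arrays A and B alone. Of the 6 genes read on arrays A and B, 3 fell and 3 did not pass, and 4 passed adjusted over the list alone. Mmp9 fell most, followed by Acp5, the tartrate-resistant acid phosphatase (650 ± 208 to 128 ± 77.9, log2 fold -2.32, SE 0.20, adjusted p = 0.000899), and Ctsk, the collagen-degrading cathepsin K (log2 fold -1.32, SE 0.12, adjusted p = 3.69e-05). A probe set of Acp5 on array A fell by 2.67 on the log2 scale. Within scan batches the medians of 7 genes were -0.77 and -1.19. The macrophage and leukocyte list did not pass (median 0.02, adjusted p = 0.954, within-batch medians -0.02 and -0.06), but was called higher without Runx2-null replicate 2 (0.0371). Of its 9 genes on arrays A and B, 0 passed over all probe sets and 4 adjusted over the list alone; the lysosomal marker Cd68 had a log2 fold of -0.58 (SE 0.18, adjusted p = 0.107).

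Mmp9 and Mmp13 were the 2 members that fell in the list of matrix proteases and inhibitors, where 12 of 14 genes on arrays A and B did not pass and 5 passed adjusted over the list alone. The list had a median of -0.24 and a mean of -0.79 (adjusted p = 0.00187 without and 0.00533 with the block, and 0.404 with an estimated correlation). The median was -0.01 without wild-type replicate 1, -0.41 without wild-type replicate 2, -0.36 without Runx2-null replicate 1 and -0.07 without Runx2-null replicate 2. On arrays A and B alone with the block it did not pass (adjusted p = 0.0791), nor without cross-hybridizing suffixes (0.0748), with medians of -0.11 and -0.01 within scan batches 1 and 2. In the mineralization and phosphate list, Ibsp and Alpl fell and 5 of 7 genes on arrays A and B did not pass, and 4 passed adjusted over the list alone. Its median was -0.61 (adjusted p = 0.000219 without and 0.00365 with the block, and 0.404 with an estimated correlation), and within scan batches it was -0.74 and -0.86. Without 1 pool this median was -0.27 and -1.0 (wild-type replicates 1 and 2) and -1.19 and -0.35 (Runx2-null replicates 1 and 2), with the list called lower each time, and it was -0.32 without the filter or with the 60th percentile filter.

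The cartilage matrix and chondrocyte list did not pass (median log2 fold 0.09, adjusted p = 0.0613, and 0.0609 with the block). Of its 22 genes on arrays A and B, 1 rose, 1 fell and 20 did not pass; adjusted over the list alone, 5 passed. Acan, the major cartilage proteoglycan, had signals of 2360.0 ± 404 and 2196 ± 351 (log2 fold -0.10, SE 0.07, adjusted p = 0.525). Sox9, a regulator of chondrocyte identity, had a log2 fold of -0.16 on array B (SE 0.16, adjusted p = 0.692). A second Sox9 probe set on array B had 0.06, and those on array C as labelled had values from -0.38 to 0.75. Hapln1, which links aggrecan to hyaluronan, fell by 0.71 on the log2 scale (SE 0.10, adjusted p = 0.00177), and the secreted cartilage protein Mia rose by 0.50 (SE 0.08, adjusted p = 0.00688). The Col2a1 probe set was below the filter, with signals of 26.4 and 5.7 in wild type and 10.5 and 9.1 in the Runx2-null pools. The gene was therefore not tested, and these signals do not show how much of its transcript was present. On array C as labelled, Chst11, a chondroitin sulfotransferase, had a log2 fold of 1.33 (adjusted p = 0.0174 with the block), and Col9a3 had 0.87 (adjusted p = 0.0909) against 0.27 on array A. Within scan batches the medians on arrays A and B were 0.19 and 0.00. On arrays A and B alone the list had a median of 0.07 (camera adjusted p = 0.406 without and 0.247 with the block). The list was called higher without wild-type replicate 2 (adjusted p = 0.000171), without Runx2-null replicate 1 (0.0314) and when all probe sets of a gene were averaged (0.00514).

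Among connective tissue genes, changes went both ways. In the tendon and fibrous connective tissue list, 17 genes were read on arrays A and B, of which 3 rose, 2 fell and 12 did not pass, and 8 passed adjusted over the list alone. The small proteoglycan genes Dcn (log2 fold 0.79, adjusted p = 0.000793), Ogn (0.65, adjusted p = 0.00400) and Kera (1.09, adjusted p = 0.0374) rose, while Col5a2 (-0.47, adjusted p = 0.0225) and the matrix glycoprotein gene Tnc (-0.43, adjusted p = 0.0440) fell. On array C as labelled, the tendon gene Tnmd had -1.68 and the proteoglycan gene Bgn had 1.13, but Bgn probe sets on array A had 0.23 (adjusted p = 0.119) and 0.00. The list as a whole did not pass (median -0.12, mean -0.02, adjusted p = 0.978, and 0.754 with the block), with within-batch medians of 0.01 and -0.14. Its median turned with the pool left out, to 0.16 without wild-type replicate 1, -0.25 without wild-type replicate 2, -0.36 without Runx2-null replicate 1 and 0.24 without Runx2-null replicate 2. In the joint and articular list, Sfrp2, a secreted Wnt modulator, rose by 0.66 (adjusted p = 0.00667) and 4 of 5 genes on arrays A and B did not pass; 1 passed adjusted over the list alone. Osr1 had a log2 fold of 0.50 (adjusted p = 0.256), and Wnt4, on array C as labelled, had 0.31 against 0.05 on array A. The list's median was 0.29 (adjusted p = 0.220, and 0.0995 with the block), and 0.43 and 0.15 within scan batches.

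Single members changed in several signalling lists, none of which passed as a list with or without the block. Among 19 BMP and TGF-beta genes on arrays A and B, Tgfb1 (log2 fold -2.29, SE 0.30, adjusted p = 0.00131), Bmp6 and Bambi, a membrane inhibitor of the pathway (-1.51, SE 0.30, adjusted p = 0.0448), fell, and Gdf10 rose by 0.61 (SE 0.15, adjusted p = 0.0485); 7 passed adjusted over the list alone. Among 12 Wnt targets and antagonists, Dkk1 (log2 fold -2.12, SE 0.42, adjusted p = 0.0199) and Apcdd1 (-1.05, SE 0.18, adjusted p = 0.00917), both Wnt inhibitors, fell, Sfrp2 rose, and 4 passed adjusted over the list alone. Frzb, a secreted Wnt antagonist, had a log2 fold of 1.99 on array C as labelled, and a dimmer probe set on array A rose by 0.75 (adjusted p = 0.00640). Of 8 hedgehog genes, Ihh fell, Gas1, a hedgehog co-receptor, rose by 0.60 (SE 0.09, adjusted p = 0.00536), and 5 passed adjusted over the list alone. Ptch1, the hedgehog receptor and target, had a log2 fold of -0.70 (SE 0.16, adjusted p = 0.0635) on its brightest probe set, and a probe set on array A fell by 1.22 on the log2 scale (adjusted p = 9.69e-05). Of 10 FGF signalling genes, 0 passed over all probe sets and 1 adjusted over the list alone; the transcription factor gene Etv5 had 0.86 (adjusted p = 0.0909), and Fgfr1, on array C as labelled, had -0.34 against 0.22 on array A. List medians were -0.18 for BMP and TGF-beta (adjusted p = 0.146), -0.08 for Wnt (0.461), 0.04 for hedgehog (0.950) and 0.09 for FGF (0.978). For hedgehog the mean was -0.05 and camera's direction was down without the block and up with it. Within scan batches the medians were -0.25 and -0.16, -0.19 and -0.49, -0.01 and -0.17, and 0.09 and 0.18 in the same order. Without the block on arrays A and B alone, the BMP and TGF-beta list (adjusted p = 0.0138) and the Wnt list (0.0339) were called lower. Both calls were lost there with an estimated correlation (adjusted p = 0.355 each) and with the block (0.0684 and 0.131).

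Markers of other cell types gave few calls. None of the lists endothelial (median -0.22, adjusted p = 0.239), erythroid (0.02, 0.978), skeletal muscle (0.04, 0.470), neural and Schwann cell (-0.02, 0.978), epidermis (-0.02, 0.978) and adipocyte (-0.34, 0.220) passed, nor did any with the block. Within scan batches their medians were -0.20 and -0.28, -0.17 and -0.01, 0.26 and -0.18, 0.41 and 0.08, -0.13 and 0.40, and -0.57 and -0.10. The endothelial list was called lower without wild-type replicate 2 (adjusted p = 0.0205) or Runx2-null replicate 1 (0.0176), and on arrays A and B alone (0.0225). Its median was -0.06 without wild-type replicate 1 (0.971) and 0.02 without Runx2-null replicate 2 (0.687), so its sign turned on 1 pool. The call on arrays A and B alone was lost with an estimated correlation (adjusted p = 0.733 without and 0.573 with the block). The mean and median differed in sign for skeletal muscle, and camera's direction was opposite to the median for erythroid, skeletal muscle, neural and epidermis. On arrays A and B, 0 of 16 endothelial, 9 erythroid, 20 skeletal muscle, 8 neural and 5 epidermal genes passed; adjusted over the list alone the counts were 2, 1, 0, 0 and 0. Values with the block were -0.52 for Emcn (adjusted p = 0.175), an endothelial sialomucin, -0.29 for the embryonic globin Hbb-y (0.0961), 0.42 for the growth cone gene Gap43 (0.257), and 0.28 and 0.27 for the keratins Krt10 (0.615) and Krt15 (0.647). Of 3 adipocyte genes, Scd1, a fatty acid desaturase, fell by 1.24 on the log2 scale (SE 0.11, adjusted p = 4.51e-05) and was the 1 gene that passed adjusted over the list alone, and Lpl had -0.34 (adjusted p = 0.377). On array C as labelled, log2 folds were -1.49 for Tnni1 and -0.82 for Mylpf, both of skeletal muscle, 1.01 for Gpihbp1, 0.37 for Slc4a1, -0.46 for Elavl3 and 1.09 for Laptm5. Probe sets of the same genes on array A had 0.07 for Tnni1, 0.21 for Mylpf, -0.21 for Slc4a1, and -0.36 and -0.04 for Laptm5. Skeletal muscle genes were lower in replicate 2 than in replicate 1 of both genotypes on arrays A and B, with medians of -1.53 in wild type and -1.87 in the Runx2-null pools, and the list was called lower without wild-type replicate 2 (adjusted p = 0.000112) or Runx2-null replicate 1 (2.55e-07) and higher without Runx2-null replicate 2 (0.000186).

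The ribosomal list was called higher and the early response list lower, by small medians, and neither call held in every setting. The cytosolic ribosomal protein list had a median log2 fold of 0.26 over 15 genes (adjusted p = 0.00154 without and 0.00201 with the block, and 0.404 with an estimated correlation), but 0.04 after quantile normalization (adjusted p = 0.277), and it was not called without wild-type replicate 1 (0.107) or Runx2-null replicate 1 (0.0783), nor when all probe sets of a gene were averaged (0.0580). Rps4x rose by 0.32 (SE 0.07, adjusted p = 0.0336; a second probe set on array A had 0.03), 10 of 11 genes on arrays A and B did not pass, 9 passed adjusted over the list alone, and Rps20, on array C as labelled, had 0.56. Within scan batches the medians were 0.32 and 0.22. The immediate early and heat shock list had a median of -0.23 (adjusted p = 0.0490 without and 0.0446 with the block, and 0.404 with an estimated correlation) and within-batch medians of -0.22 and -0.17, and it was not called when any 1 of the 4 pools was left out (adjusted p from 0.0923 to 0.204), with either other filter (0.0627 and 0.126), without cross-hybridizing suffixes (0.0748) or with averaged probe sets (0.0708). Of its 18 genes, the immediate early gene Fos fell by 0.88 on the log2 scale (SE 0.20, adjusted p = 0.0348), 17 did not pass, and 1 passed adjusted over the list alone. Btg2 had -0.45 (adjusted p = 0.14).

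The lists of the cell cycle (median -0.01, adjusted p = 0.673), hypoxia and glycolysis (0.08, 0.220) and limb patterning genes (0.06, 0.843) did not pass with or without the block, and had within-batch medians of -0.07 and 0.05, 0.05 and 0.11, and 0.30 and 0.27. Of 23 cell cycle and 15 hypoxia and glycolysis genes on arrays A and B, 0 passed over all probe sets, and 0 and 1 adjusted over the list alone. On array C as labelled, Mcm5 had -0.60 (0.13 on array A), Tk1 had -0.56 (-0.17 on array A), Car9 had 0.71, and the oxygen-sensing hydroxylase gene Egln3 had 1.03 (adjusted p = 0.0498 with the block) against 0.61 on array B (0.187). Among 12 limb patterning genes, the T-box gene Tbx2 fell by 0.98 on the log2 scale (SE 0.18, adjusted p = 0.0147), Tbx15 rose by 0.64 (SE 0.14, adjusted p = 0.0348), and 3 passed adjusted over the list alone; Hoxd10, on array C as labelled, had 1.23 against 0.58 on array A.

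**Figure D2:**
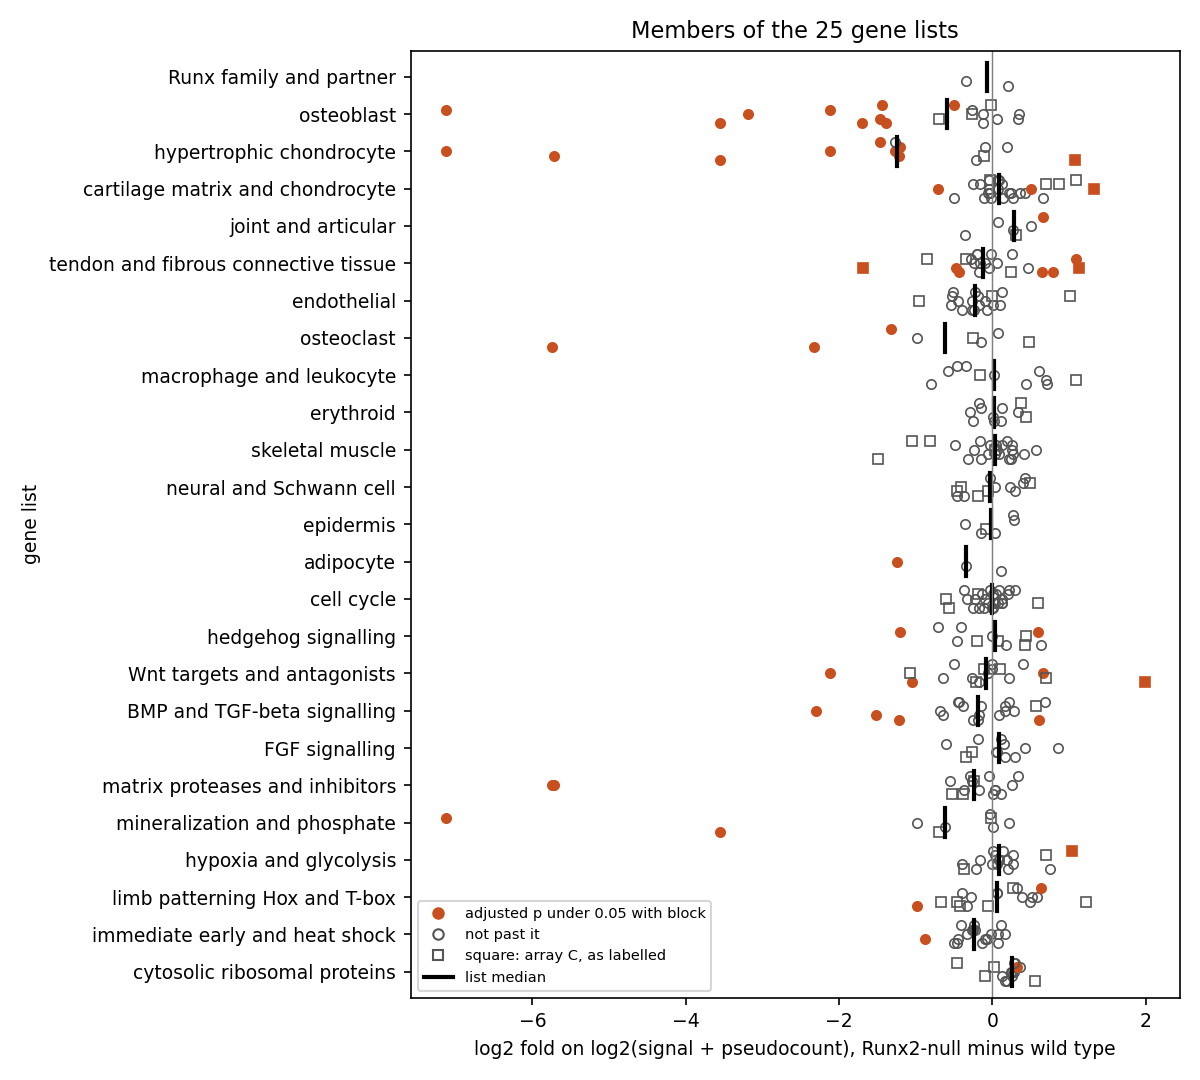
Log2 fold on the log2(signal + pseudocount) scale, Runx2-null minus wild type, of each tested member of the 25 gene lists. Filled orange points passed an adjusted p of 0.05 with the replicate block, squares are from array C as labelled, and bars are list medians, which lie lowest for the hypertrophic chondrocyte list at -1.24.

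Outside the lists, the 12 largest falls on arrays A and B with the block also took in Thy1, a surface glycoprotein of stromal and immune cells (59.6 ± 40.9 to 3.45 ± 0.35, log2 fold -2.52, adjusted p = 0.00465), Gm4788 (-2.45, adjusted p = 0.00286), Pltp, which transfers phospholipids between lipoproteins (207 ± 18.8 to 32.8 ± 9.62, log2 fold -2.44, adjusted p = 9.29e-06), the chemokine gene Ccl9 (-2.34, adjusted p = 0.000370) and Serinc5 (-2.25, adjusted p = 0.0121). The 12 largest rises were smaller. Gstt1, a glutathione transferase, rose by 1.55 (7.70 ± 1.98 to 37.0 ± 14.8, adjusted p = 0.0465), Rab27b, a GTPase of secretory vesicles, by 1.45 (adjusted p = 0.0334), Selenbp1 by 1.25 (adjusted p = 0.00786), and Ppp1r9a, which encodes the actin-binding protein neurabin, by 1.24 (adjusted p = 0.00894). Gstt1 in wild type, and Thy1 and Gm4788 (mean 3.60) in Runx2-null, lay near or below the pseudocount of 7. So did Ccl9 in Runx2-null replicate 2 (signal 3.7). The size and rank of the folds of these genes are therefore not known exactly. Dcx, a microtubule-binding protein of migrating neurons, rose from 56.1 ± 10.8 to 138 ± 17.0 (log2 fold 1.20, adjusted p = 0.00135), and Dio2, a deiodinase that activates thyroid hormone, from 28.5 ± 3.11 to 72.4 ± 21.2 (1.14, adjusted p = 0.0254). The remaining 6 were 6330403K07Rik (1.10), Zfp507 (1.09), Kera (1.09), Smim27 (1.06), Rasa4, a Ras GTPase activator (0.94), and Lrrc75b (0.92). On array C as labelled, other probe sets had log2 folds of -1.52 for Zfp507 and -0.76 for 6330403K07Rik, opposite to their rise. Smim27 differed more between the replicates than between genotypes, with signals of 18 and 229 in wild type and 53.9 and 471 in the Runx2-null pools. Of 81 other tested probe sets on arrays A and B for the genes called with the block, 71 had the same sign. Genes were ranked by their brightest probe set only, so a larger fall of a dimmer one did not count. For example, Sgms2 was ranked by a log2 fold of -1.97, while another probe set on array B fell by 3.68 (limma adjusted p = 0.000142 with the block).

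Array C carried the 2 remaining calls of the fit without a block and most of the genes next in order of p, all as labelled. Iqgap1, a scaffold of the actin cytoskeleton, went from 883 ± 65.6 to 192 ± 17.3 (log2 fold -2.15, SE 0.17, adjusted p = 0.0469), but its 3 probe sets on array A had log2 folds of -0.30, -0.10 and 0.00. A Dact3 probe set had -3.25 (adjusted p = 0.0469), while the gene's brightest probe set, on array B, had -0.06 (adjusted p = 0.999). The other genes that filled the rule had an adjusted p of 0.0539 to 0.0901 without the block. The 6 with lower values were Vwa5b1 (log2 fold -1.99), Rhoq (-1.74), Celf2 (-1.69), Spin1 (-1.53), Plin4 (-1.51) and Hspb2 (-1.31). None of the probe sets of these genes on arrays A and B passed with the block, with log2 folds of 0.02 for Rhoq, -0.06 to 0.59 for Celf2, -0.61 to 0.22 for Spin1, and 0.09 and 0.14 for Hspb2. The 12 with higher values were Wdr24 (3.08), Cluap1 (2.23), Frzb (1.99) and, between 1.51 and 1.17, Proser2, Cldn12, Dhx40, Gabpb1, Man2a2, Eri3, Bms1, Eif2b4 and Mcl1. Of these, Frzb rose on array A too, by 0.75, while probe sets on arrays A and B that did not pass had 0.19 for Proser2, -0.10 for Dhx40, 0.16 for Gabpb1, 0.29 for Man2a2, -0.09 and -0.00 for Eri3, 0.16 for Bms1, 0.08 for Eif2b4 and 0.04 for Mcl1. With the block, 162 of 7592 probe sets on array C passed (82 higher, 80 lower).

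The control probe sets of array C grouped differently from those of arrays A and B. On arrays A and B, arrays with the same number were close, at a root-mean-square log2 distance of 0.33 and 0.46 over 66 control probe sets, against 1.17 and 1.03 between arrays of the same genotype. On array C the distance was 1.17 for the same number and 0.55 for the same labelled genotype. The 5' probe set of 18S ribosomal RNA read 446 and 543 in batch 1 and 38.5 and 31.3 in batch 2 on array A, but 1546 and 2019 in wild type and 173 and 129 in Runx2-null on array C. The ratio of 3' to 5' Actb signal, a sign of transcript length in the labelled RNA, was 1.06 to 1.13 in batch 1 and 1.62 to 1.95 in batch 2 on arrays A and B, while on array C it was 1.10 and 1.08 in wild type and 1.61 and 1.84 in Runx2-null. Whole profiles followed the same order: the correlation over probe sets, which are not independent, was 0.960 for the same number and 0.914 for the same genotype on array A, 0.919 and 0.844 on array B, and 0.855 and 0.902 on array C.

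**Figure D3:**
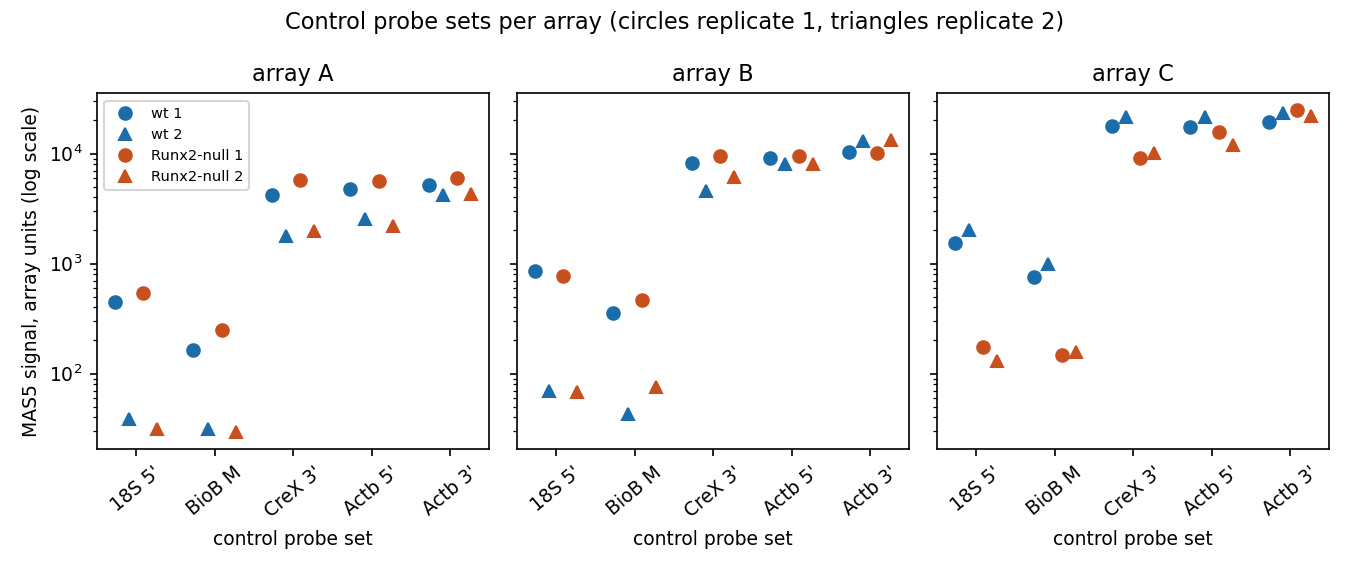
Signals of 5 control probe sets on a log axis, in array intensity units, on the 4 arrays of each type; circles are replicate 1, triangles replicate 2, blue is wild type and orange is Runx2-null. On arrays A and B the 18S and BioB probe sets part by replicate number, and on array C by labelled genotype.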

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

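Arrays A and B alone, array C with exchanged labels, and the block combined with other settings were chosen after the data had been seen; the other alternatives were planned. The fit without a block called 6 probe sets. The count was 11 (2 higher, 9 lower) with quantile normalization, 2 with the pseudocount divided by 4, 13 (3 higher, 10 lower) with 4 times the pseudocount, 11 (2 higher, 9 lower) with the 60th percentile filter, 2 without the variance trend, 3 in 1 joint fit of the array types, 10 (2 higher, 8 lower) without cross-hybridizing suffixes, and 99 (45 higher, 54 lower) with adjustment within each array type, 95 of these on array C. Leaving out 1 pool gave 5 to 22 calls, with 22 without wild-type replicate 1 and 11 without Runx2-null replicate 1, and the array A calls remained among them each time, while Iqgap1 was lost each time. The gene Mmp9 (adjusted p = 0.0585 and 0.0980) and the gene Mmp13 (0.0585 and 0.162) lost the call with the smaller pseudocount and without the trend, and Mmp13 also in the joint fit (0.0520). The replicate block gave 505 calls, and 343 on arrays A and B alone. With an exchanged pair of labels on array C the count was 3, and 289 with the block; same-numbered deviations on array C as labelled correlated at 0.06. The count of probe sets changed on arrays A and B with the replicate block, 343, became 522 with 4 times the pseudocount, 95 without the filter, 6 without the variance trend and 4 in the joint fit, and lay between 275 and 448 in the other settings. Their share of higher calls, 41.1%, fell to 21.1% without the filter and to 0% in the 2 fits with few calls. Of the 24 gene lists 7 passed, and 0 with an estimated correlation; over all 3 array types the lowest adjusted p of fry was 0.0792 without and 0.0525 with the block. Without the block on arrays A and B alone, fry gave 0.0347 for 7 lists, which were hypertrophic chondrocyte, osteoclast, adipocyte, BMP and TGF-beta, mineralization, and immediate early, all lower, and limb patterning, higher. After quantile normalization it gave 0.0263 for hypertrophic chondrocyte and adipocyte. Over all 3 array types the block changed no list call; on arrays A and B alone it ended those of BMP and TGF-beta (adjusted p = 0.0138 without and 0.0684 with it), Wnt (0.0339 and 0.131) and matrix proteases (0.0193 and 0.0791). Among lists that did not pass, the sign of the median turned on 1 pool for cartilage, tendon, endothelial, macrophage, erythroid, skeletal muscle, neural, epidermis, cell cycle, hedgehog, FGF and limb patterning. Some named genes that did not pass without the block had a sign that depended on 1 pool, with leave-one-out log2 folds of -0.78 to 0.10 for gene Runx1, -0.38 to 0.068 for gene Sox9, -0.28 to 0.0726 for gene Acan, -0.14 to 0.53 for gene Vegfa, -0.21 to 0.74 for gene Krt15 and -0.43 to 2.54 for gene Smim27. Fits that left out a pool assumed that the lone pool varied like the other genotype's. Leaving out a pool under the block leaves no residual degrees of freedom, so it was not run, and the scan batch was not run as a separate block because it equals the replicate number. No alternative was run for Runx2, which is not analysed here. The cause of these shifts was not tested, except that fewer or more probe sets enter under another filter. Signals near the pseudocount limit how exactly the folds of some genes are known. These include Ibsp, Mmp9, Mmp13, Dmp1, Thy1 and Gm4788 in the Runx2-null pools and Gstt1 in wild type. The same holds for Tgfb1 in Runx2-null replicate 1 (signal 6.3) and Ccl9 in Runx2-null replicate 2 (3.7).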

Other observations

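The tests of array C, bone genes, scan batch and muscle, and all values for arrays A and B alone, were chosen after results had been seen; the tests of imprinted and sterol genes were fixed before theirs, but the demand that they hold under quantile normalization too was added after those values were seen. On arrays A and B alone, 14 of 17 endothelial genes had lower values in the Runx2-null pools, with a median log2 fold of -0.24 (camera adjusted p = 0.0225 without and 0.0119 with the block). With an estimated correlation this was adjusted p = 0.733 and 0.573. Within scan batches 1 and 2, 12 and 15 of the 17 genes were lower, and single genes such as Eng (-0.40, adjusted p = 0.0814), Cdh5 (-0.54, 0.104) and Tie1 (-0.52, 0.225) did not pass with the block.

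A look through all calls on arrays A and B raised 2 themes, which were then tested on other genes of the same kind; they are hypotheses, picked from many possible themes. Scd1, Fasn (log2 fold -0.76, adjusted p = 0.00161), Fdps (-0.62, adjusted p = 0.00231) and Hmgcs1 (-0.54, adjusted p = 0.0227), which make fatty acids or sterols, fell. Of 27 other tested genes of these pathways 19 had lower values, 15 of them in both scan batches. Their median of -0.18 lay at percentile 0.12 of 10000 random lists matched on mean signal (-0.19 and percentile 0.05 after quantile normalization), which met the test. For both themes, random lists treat genes as independent and do not measure the spread between pools. Several synthesis genes moved together between the wild-type pools by far more, such as Sqle (238 and 473) and Acly (430 and 1134), while Ebp (60.5 and 56.7) did not. Whether synthesis genes as a group are lower in the Runx2-null humeri therefore stays a hypothesis. The imprinted genes Meg3 (0.75, adjusted p = 0.000195), Dlk1 (0.46, adjusted p = 0.00482), Igf2 (0.30, adjusted p = 0.0377) and Nnat (0.64, adjusted p = 0.0498) rose. Further Meg3 probe sets had log2 folds from -0.31 to 0.89 on arrays A and B, and from -1.21 to 0.79 on array C as labelled. Of 29 other imprinted genes 21 had higher values, 14 in both scan batches, with a median of 0.15 at percentile 98.94, which met the test as first fixed, beyond the central 95% of the random lists (-0.10 to 0.13). After quantile normalization the median was 0.08 at percentile 91.3, which did not, so this theme stays open. Ppp1r9a, an imprinted gene among the largest rises, was left out of both sets.

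Array C grouped by labelled genotype where arrays A and B grouped by scan batch. If the values of wild-type replicate 2 and Runx2-null replicate 1 had been exchanged on array C, the genotype fold of arrays A and B should appear there between arrays of 1 labelled genotype; over 44 called genes shared with array C it correlated at r = 0.185 (95% bootstrap interval -0.09 to 0.41) with the wild-type difference and at 0.409 (0.11 to 0.64), above 0, with the Runx2-null difference. If the labels hold and arrays of 1 genotype were hybridised together, the fold should appear in the labelled comparison, where r was 0.0990 (-0.22 to 0.38), against 0.715 for calls of array A read on array B over 59 genes. An exchange needs both differences to carry the fold and only 1 interval lies above 0. The intervals over 44 genes overlap and genes are not independent, so these correlations exclude neither and do not tell an exchange from a separate hybridisation. The 4 skeletal muscle genes on array C had median differences of 0.15 and -0.11 between replicates and -0.93 between labelled genotypes, where the muscle difference on arrays A and B lay between replicates (-1.53 and -1.87). Of the 4, Ckm (0.03) did not differ between labelled genotypes. Hybridising the arrays of 1 genotype together would not by itself remove the difference between replicates. For these 4 genes the values argue against that explanation, but they do not establish an exchange. The ratio of 3' to 5' Actb signal moved in the same way. For wild-type replicate 2 it was 1.68 on array A and 1.62 on array B, but 1.08 on array C. For Runx2-null replicate 1 it was 1.06 on arrays A and B, but 1.61 on array C. These ratios do not establish an exchange either. Under an exchange, the labelled genotype folds of array C would be differences between replicates 2 and 1.

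On arrays A and B, 9 of 15 osteoblast and 8 of 12 hypertrophic chondrocyte genes fell. Ibsp, Alpl, Pth1r and Dlx5 count in both, so the lists are not separate results. Both lists were called lower there by camera, but not with an estimated correlation (adjusted p = 0.355 and 0.235 without and 0.573 each with the block). Of differences in tissue content, only dilution of the Runx2-null humeri by tissue without cartilage transcripts was tested. Such dilution would lower cartilage genes by about as much. Their median was 0.0733 (95% bootstrap interval over genes, not pools, -0.05 to 0.22) against -1.38 (-1.69 to -0.12) for osteoblast genes, which argues against it. A scan batch effect shared by both genotypes cannot give the fold, since both genotypes lie in each batch. The 27 genes of both lists had medians of -0.545 and -1.27 within the 2 batches, and 21 of them were lower in both. Why the medians differed in size between the batches was not tested. A candidate explanation is that Runx2-null humeri hold fewer or less mature osteoblasts and hypertrophic chondrocytes, or that each such cell makes less of these transcripts; bulk RNA does not separate these, and neither was tested.

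Skeletal muscle genes were lower in replicate 2 than in replicate 1 in both genotypes on arrays A and B, by medians of -1.53 and -1.87 over 24 genes. Both medians lay at percentile 0 of 10000 matched random lists. The central 95% of these ran from -0.38 to 0.20 in wild type and from -0.30 to 0.24 in Runx2-null. This argues against a general effect of the scan batch on all probe sets of that brightness. The list was picked because its difference had been seen, and random lists treat genes as independent, so the percentile overstates the evidence. A batch effect on particular kinds of probe sets is not covered. Other lists were lower in replicate 2 of wild type and Runx2-null too, by less, with medians of -0.64 and -0.73 for macrophage and leukocyte, -0.50 and -0.42 for tendon, -0.53 and -0.43 for FGF and -0.35 and -0.51 for endothelial genes, and the ratio of 3' to 5' Actb signal differed between the batches. Different amounts of soft tissue in the preparations, or RNA quality, may account for the muscle difference; neither was tested, nor was a biological explanation, which the design does not give.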
